A study of Homo sapiens with 6 samples.

How the data were processed

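RNA from 6 CUTLL1 cultures was analysed, 3 with AURKB shRNA and 3 with a control shRNA. Groups and replicate numbers were taken from the sample titles. The cells were kept for 48 h after infection, with puromycin selection per the labels' protocols. The authors deposited whole-number counts per Ensembl gene for 50868 genes in each library. The authors also deposited FPKM for the same genes, which equal the counts divided by 1 length per gene and 1 depth per library (largest relative deviation 2.69e-05 over 12320 genes). Alignment with HISAT2 2.0.4 and assembly or quantification with StringTie 1.3.0 on GRCh38 (hg38) are named, with edgeR, per the submitters' processing notes. The role of each tool, the strand setting and the handling of reads that map to several places are not given in the sources used here. Reads of overlapping, antisense or near-identical genes therefore cannot be told apart. Of the genes, 50111 matched GENCODE release 29 by identifier and 47538 had the identical position. A total of 28 gene names had been turned into dates by a spreadsheet, and genes were matched by identifier.

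Library totals ran from 10154187 to 11922979 counts. Counts were filtered with filterByExpr (minimum count 10, minimum total 15), which left 14818 genes holding 99.65% to 99.8% of each library's counts, and scaled by TMM (factors 0.9789 to 1.0204). The arms were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with the arm as the single term, two-sided, Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Every adjusted p of a gene comes from this test unless another is named. A fold minimum of 2 was applied after the test to describe size. Values in CPM are TMM-scaled, except marker sums and the genes seen in 1 library, which use the total count. The biological coefficient of variation was 0.127. Between replicates of an arm, chi-square per degree of freedom was 6.92 to 7.91, so no library was a copy of another. Intervals and floors (3 counts) cover counting error only, since the reads carry no stated molecular identifiers.

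Before the data were examined, 22 gene lists and the rule for named genes were fixed. The rule names AURKB, INCENP, BIRC5, CDCA8, AURKA and MYC. It adds the 6 genes with the largest rise and the 6 with the largest fall among genes with a symbol, an adjusted p below 0.05, a mean of at least 1 CPM in the higher arm and no overlap between the arms. It further adds, per list, the 2 called members with the largest change or, with none called, the member with the smallest p. "Symbol" was read as an HGNC symbol in the file's description column (30759 genes) once the file had been seen. The other reading would have put AC007192.4, CTD-3074O7.11, CTD-2278I10.6 and RP11-47I22.4 (log2 fold change 3.20) among the rises and RP11-1055B8.4 (-2.91, or -3.6 without shAURKB replicate 3) among the falls. A gene that the rule names is not reported here. Other genes named in the text were chosen after their values were seen. The lists were compared with other genes by camera of limma 3.58.1 (preset inter-gene correlation 0.01, and an estimated correlation). fry tested whether each list moved on balance one way, without comparison to other genes. Lists with fewer than 3 tested genes had no list test. A further 5 lists were added after the data were seen.

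The tests were run on simulated counts drawn from the real means, library sizes and dispersions of the 14818 genes, with 200 genes changed. The MYC-induced list's members outside these 200 were shifted upward too, and count as changed in the shares of unchanged genes. The edgeR test recovered 0% of genes changed 1.25-fold, 38% at 1.5-fold, 74% at 2-fold and 88% at 4-fold, and 7.1% of its calls were unchanged genes. These shares need not hold for the real comparison, where 3456 genes were called and the Benjamini-Hochberg cut was therefore less strict. The bar first set for the 4-fold genes was above 90%, which the test missed. The simulation and its seed were kept. Of the 6 genes missed, 3 had been removed by the filter and 3 had low or variable counts. The bar was then replaced by limits on the error of the estimates, whose median at 4-fold was 0.034, and on calls of the wrong sign. In the same simulation 19.3% of DESeq2's calls and 5.7% of limma-voom's were unchanged genes. camera called the shifted list and 0 of 18 unshifted lists. The simulated genes were drawn independently of each other, so this cannot show how often camera calls unshifted lists of correlated genes.

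Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter, at least 1 CPM in 3 libraries, the replicate number as a block, each library left out, and limma-trend on log2(FPKM + 1) after a minimum of 0.5 FPKM in 3 libraries. The FPKM comparison was repeated with a pseudocount of 0.1 and without the filter. Centring the named genes on the median of genes with at least 10 CPM (0.04) was added after seeing the data. Upper-quartile factors moved the median gene by -0.054 and DESeq2 by 0.013 on the log2 scale. A trend of fold change on abundance, length and GC content was fitted over 11502 protein-coding genes with natural splines of 4 degrees of freedom.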

Results

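Gene expression was measured by RNA sequencing in CUTLL1, an established human T-cell acute lymphoblastic leukaemia (T-ALL) line, after lentiviral delivery of a short hairpin RNA (shRNA). One arm received an shRNA against AURKB (shAURKB) and the other a control shRNA named for GFP (shGFP), and total RNA was taken after 48 h. Each arm held 3 libraries, described as biological replicates in the series' design text. The total count was 10421370, 10154187 and 11922979 in shGFP replicates 1 to 3 and 11641019, 10446722 and 10795436 in shAURKB replicates 1 to 3. The first principal component of the log counts held 41.9% of the variance, and on it the 3 shAURKB libraries lay apart from the 3 controls. One control library stood apart in a small set of genes. In shGFP replicate 1, 120 genes had at least 5 reads and none in any other library, against 4 to 10 such genes in each of the others, and markers of fibroblasts and epithelia summed to 28.69 CPM there (17.8 CPM of it COL1A2) against at most 1.55 CPM elsewhere, where CPM scales reads to a common library size. None of these markers reached the tested set.

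The series title concerns MYC stabilisation by Aurora B, the mitotic kinase encoded by AURKB, so the target itself, its partners and MYC mRNA were compared first. RNA sequencing gives mRNA levels alone, so MYC protein, whose stability the title concerns, was not measured here. AURKB (ENSG00000178999, GRCh38 chromosome 17, 8204733 to 8210600, minus strand) fell in every shAURKB library. Its level was 39.9 ± 3.93 CPM (SD, n = 3) with AURKB shRNA and 101 ± 5.1 CPM (SD, n = 3) with control shRNA, with library values of 36.0 to 43.9 CPM against 97.0 to 107 CPM. The log2 fold change was -1.35 ± 0.08 (SE), which left 39.3% of the control level (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.54e-04). MYC mRNA (ENSG00000136997, chromosome 8, 127735434 to 127741434) was 12.5 ± 4.33 CPM with AURKB shRNA and 11.6 ± 1.23 CPM with control shRNA (n = 3 each). Its log2 fold change of 0.12 ± 0.25 (SE) did not pass the test (edgeR adjusted p = 0.778), and its sign turned to -0.13 without shAURKB replicate 1. Of the partners of Aurora B in the chromosomal passenger complex, BIRC5 (survivin) rose by 0.28 ± 0.05 on the log2 scale (edgeR adjusted p = 7.49e-03). INCENP and CDCA8 (borealin) had log2 fold changes of 0.10 ± 0.10 and 0.02 ± 0.04 and did not pass (edgeR adjusted p = 0.524 and 0.755), and CDCA8 was at -0.04 with upper-quartile scaling, which lowered the median gene by 0.054. AURKA, the related spindle kinase, rose by 0.23 ± 0.07 at an edgeR adjusted p of 0.047. That call was lost when any library other than shAURKB replicate 2 was left out, and its adjusted p ran from 0.0327 to 0.124 over the alternatives. Over the list of the complex and the Aurora kinases, 5 genes were tested, 2 rose and 1 fell, the same counts as when adjusted over the list alone (camera adjusted p = 0.812). The list's median was 0.10 and its mean -0.14.

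**Figure D1:**
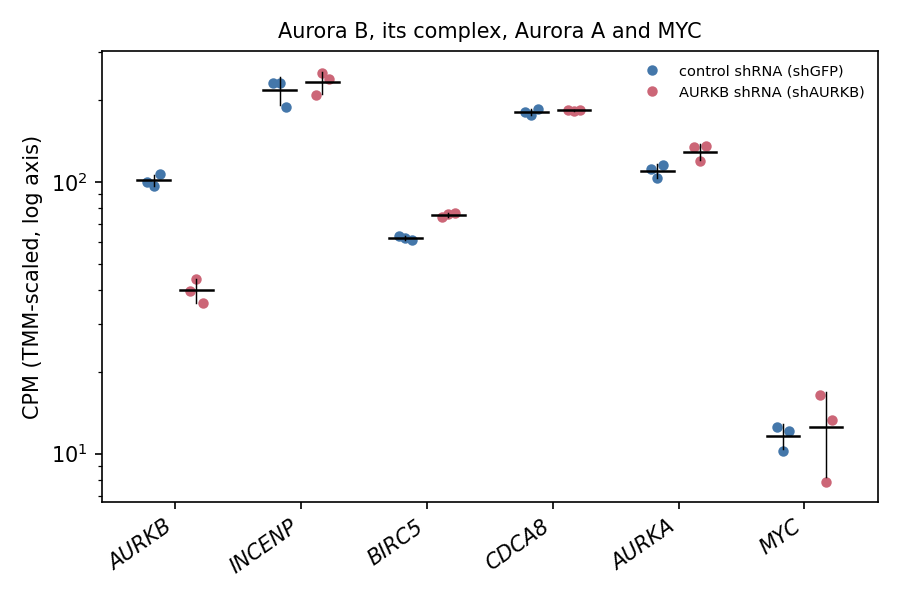
CPM per library (log axis) of AURKB, INCENP, BIRC5, CDCA8, AURKA and MYC with control shRNA (blue, n = 3) and AURKB shRNA (red, n = 3); horizontal bars are means and vertical bars 1 SD either side. AURKB was 36.0 to 43.9 CPM with its shRNA and 97.0 to 107 CPM in the controls, while the MYC values of the arms overlapped.

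Across the transcriptome, 3456 of 14818 tested genes differed between the arms: 1847 were higher (12.5%) and 1609 lower (10.9%) with AURKB shRNA at an adjusted p below 0.05. Most changes were small. Only 37 genes, 29 of them protein-coding, were higher at least 2-fold, and 268, of which 184 were protein-coding, were lower at least 2-fold. Across protein-coding genes, which are not independent replicates, the log2 fold change rose with mean log CPM (Spearman's rho 0.28). The controls also had more genes with a count, 22143 to 23044, than the shAURKB libraries, 21591 to 21816. Without the library that stood apart, shGFP replicate 1, the counts were 1294 higher and 1028 lower, with 41 and 211 at 2-fold. Leaving out any 1 library took the number of lower genes to between 998 and 1056. The groups did not overlap in 42.6% of tested genes, where chance gives 10%. Higher genes made up 53.4% of the calls, and 38.8% with upper-quartile scaling.

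Among genes with an HGNC symbol that met the naming rule, with no overlap between the arms, the strongest rises included noncoding RNAs and receptors. SLC46A1, at 3.51 ± 0.91 on the log2 scale, was left out because its arms overlapped. ATP6V1G2-DDX39B (ENSG00000254870, chromosome 6, 31530219 to 31546608), a read-through locus that shares its strand and span with DDX39B, had 556 reads with AURKB shRNA and 2 with control shRNA, a ratio of 285 with a 95% counting interval of 78.5 to 2360. Of these reads, 359 lay in shAURKB replicate 2 and both control reads in shGFP replicate 3. The ratio was 148 (40.4 to 1230) without shAURKB replicate 2, and without shGFP replicate 3 the gene was at least 61.7-fold higher against a floor of 3 counts per library. DDX39B itself had a log2 fold change of -0.18 ± 0.07 (adjusted p = 0.128). With 2728 to 3424 reads per shAURKB library, it far exceeded the read-through locus. Reads shared by both genes cannot be told apart, so the ratio may rest on how they were assigned. RN7SK, the 7SK RNA that holds the elongation factor P-TEFb (ENSG00000202198, chromosome 6, 52995620 to 52995950), rose by 3.25 ± 0.20 on the log2 scale, from 0.612 to 5.86 CPM. SNORD3A, the U3 small nucleolar RNA (ENSG00000263934, chromosome 17, 19188016 to 19188714), rose by 2.24 ± 0.37, from 0.371 to 1.77 CPM. Counts of both RNAs were low in the controls, with 6 or 7 reads per library for RN7SK and 3 or 6 for SNORD3A. How fully the libraries captured these RNAs was not tested, so both rises are stated for library reads and not for cellular levels. The prostacyclin synthase gene PTGIS (ENSG00000124212, chromosome 20, 49503874 to 49568146) rose by 2.12 ± 0.44, from 0.911 to 3.99 CPM, though its adjusted p was 0.0578 without shGFP replicate 3 (2.15e-03 to 0.0578 over the alternatives) and its rise 2.88 without shGFP replicate 1. FGFR1, a receptor for fibroblast growth factors (ENSG00000077782, chromosome 8, 38411138 to 38468834), rose by 2.07 ± 0.38, from 0.953 to 4 CPM. Of its control reads, 18 lay in shGFP replicate 1, and the rise was 2.76 without that library. The ephrin receptor gene EPHA1 (ENSG00000146904, chromosome 7, 143390289 to 143408892) rose by 1.92 ± 0.42, with an adjusted p of 0.0509 without shAURKB replicate 1 and 0.0584 without shAURKB replicate 2 (0.0182 to 0.062 over the alternatives).

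The largest falls among such genes began with GFRA4, a co-receptor gene of the GDNF family (ENSG00000125861, chromosome 20, 3659292 to 3663399). It had 42 reads with control shRNA and 3 with AURKB shRNA, a ratio of 13.7 with a 95% counting interval of 4.37 to 68.9 (adjusted p = 4.83e-03), or 26.5 (4.5 to 1070) without shAURKB replicate 1. HYDIN2, a pseudogene copy of HYDIN (ENSG00000276975, chromosome 1, 146547367 to 146914294), fell by 3.23 ± 0.57 on the log2 scale (-3.93 without shAURKB replicate 2), and its reads can be shared with its near-identical parent. FAM167A (ENSG00000154319, chromosome 8, 11421463 to 11474715) fell by 2.78 ± 0.28, from 6.24 to 0.888 CPM, and PGPEP1L (ENSG00000183571, chromosome 15, 98968230 to 99007795) by 2.63 ± 0.41, from 1.79 to 0.287 CPM, with a log2 fold change of -3.21 without shAURKB replicate 2. CHAC1 and SLC7A11, described with the stress response below, completed the 6. Several read-through loci without an HGNC symbol had no control reads at all. Against a floor of 3 counts per library, 0.274 CPM, AC007192.4 was at least 21.4-fold, CTD-3074O7.11 at least 13.2-fold and CTD-2278I10.6 at least 8.52-fold higher. Of the genes that overlap them on the same strand, DPP3 was called higher (log2 fold change 0.26, adjusted p = 0.0493), and IFI30, PIK3R2, BBS1, BABAM1 and ANKLE1 were not called. Of 68 genes with either 0 or at least 15 reads in every library, these 3 followed the arms, 44 had reads in 1 library and 21 had reads in several libraries without fully following the arms, 2 of them in shAURKB libraries alone. An example is ISY1-RAB43 with 148 reads in shGFP replicate 2, 260 in shAURKB replicate 3 and 0 in the rest. AC007192.4 had an adjusted p of 0.0549 without shAURKB replicate 2 (2.72e-08 to 0.0549 over the alternatives).

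Genes that MYC is known to induce, most of them serving the nucleolus and cell growth, rose as a group. MYC mRNA did not pass the test, but its estimate of 0.12 ± 0.25 (SE) is too imprecise to exclude a rise as large as the list's median. Of 59 tested, 46 rose, none fell and 13 were not called, and 49 rose when adjusted over the list alone. The median log2 fold change was 0.42 (1.34-fold). camera placed the list above other genes (adjusted p = 5.75e-25, and adjusted p = 3.72e-03 with an estimated correlation). HK2, the glycolytic hexokinase, rose by 0.82 ± 0.06 on the log2 scale, from 49.8 to 87.8 CPM, and RRP9, a U3 snoRNP protein, by 0.76 ± 0.07, from 43.1 to 73.1 CPM. Members named after their values were seen include the nucleolar chaperone gene NPM1 (0.57 ± 0.03), NCL (0.38 ± 0.03) and the polyamine enzyme genes ODC1 (0.44 ± 0.03) and SRM (0.60 ± 0.08). CDK4 and LDHA had values of -0.02 and 0.13 and were not called. Genes that MYC is known to repress lay lower: of 14 tested, 4 fell and 1 rose, with the same counts when adjusted over the list alone (median -0.31, camera adjusted p = 2.88e-03, but adjusted p = 0.088 with an estimated correlation). The antiproliferative gene BTG2 fell by 1.93 ± 0.19 and TXNIP, an inhibitor of thioredoxin, by 1.25 ± 0.07, while the cell cycle inhibitor gene CDKN1A rose by 0.62 ± 0.13. Among 19 genes for partners and turnover of MYC, 2 rose and 3 fell, as also when adjusted over the list alone (camera adjusted p = 0.608; median 0.01, mean -0.01, and median -0.04 with upper-quartile scaling). MAX, which encodes the dimerisation partner of MYC and overlaps FNTB on the other strand, rose by 0.87 ± 0.15. USP28, a deubiquitinase gene of the FBXW7 pathway, fell by 0.79 ± 0.08.

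Genes of the integrated stress response, which ATF4 directs under amino acid shortage, fell most broadly. Of 22 tested, 17 fell, 1 rose and 4 were not called, and 19 fell when adjusted over the list alone. The median log2 fold change was -0.54, and camera gave an adjusted p of 5.03e-24 (adjusted p = 3.72e-03 with an estimated correlation). CHAC1, a glutathione-degrading enzyme gene (ENSG00000128965, chromosome 15, 40952962 to 40956519), fell by 2.81 ± 0.23, from 23 to 3.28 CPM, 7-fold. SLC7A11, which encodes the cystine transporter subunit (ENSG00000151012, chromosome 4, 138164097 to 138242349), fell by 2.66 ± 0.11, from 82.4 ± 2.59 to 13 ± 1.88 CPM (SD, n = 3), 6.34-fold. SESN2 fell by 2.07. PCK2, ASNS and PSAT1, chosen after their values were seen, fell by 2.09, 1.25 and 1.28. ATF4 mRNA itself fell by 0.32 ± 0.04. The riser was the tryptophanyl-tRNA synthetase gene WARS (0.50), and DDIT3, at -0.42 ± 0.15, was not called (edgeR adjusted p = 0.0887).

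**Figure D2:**
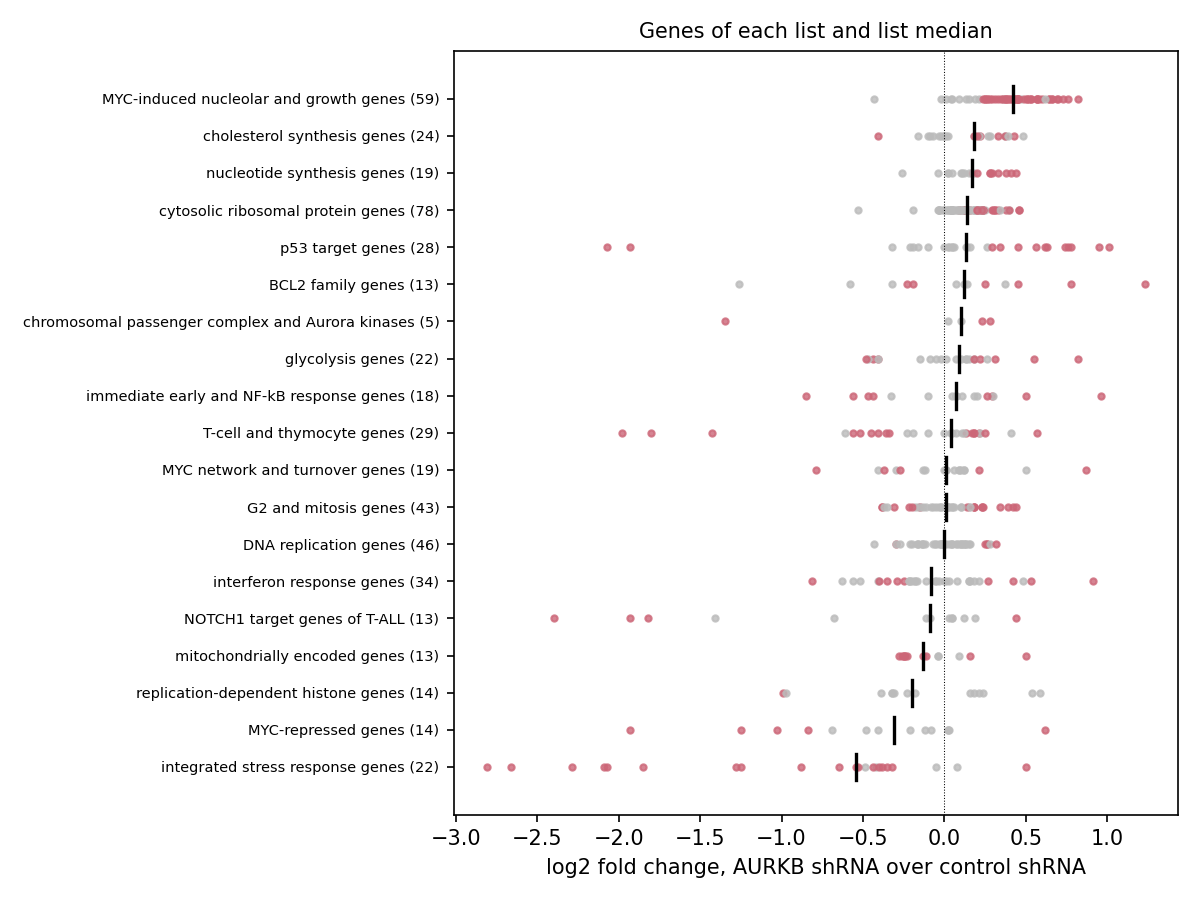
log2 fold change (AURKB shRNA over control shRNA, x axis) of each tested gene in the 19 lists with at least 3 tested genes, with the number tested in brackets; red points passed an adjusted p of 0.05, grey points did not, and the black bar is the list median. The MYC-induced list has the highest median, 0.42, and the integrated stress response list the lowest, -0.54.

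NOTCH1 is active in this leukaemia line, and its target genes were uneven. Of 13 tested, 3 fell and 1 rose, and 4 fell when adjusted over the list alone. The camera adjusted p of 0.048 was lost with an estimated correlation (adjusted p = 0.19), and without shGFP replicate 1 (adjusted p = 0.0657) or shAURKB replicate 2 (adjusted p = 0.0609). Over the alternatives it ran from 1.73e-04 to 0.388. NOTCH3, a receptor gene induced by NOTCH1, fell by 2.40 ± 0.11, from 49.9 to 9.44 CPM, and HES4 by 1.93 ± 0.24, from 3.70 to 0.965 CPM. NOTCH1 itself rose by 0.44, while HES1 (-0.09) and DTX1 (0.12) were not called. T-cell and thymocyte genes also went both ways: of 29 tested, 7 rose and 9 fell, and 10 fell when adjusted over the list alone. Their median was 0.04 (-0.01 with upper-quartile scaling) and their mean -0.22. camera did not call the list (adjusted p = 0.0707), but did so without shAURKB replicate 1 (adjusted p = 0.0467), with upper-quartile scaling (adjusted p = 0.0366) and with no low-count filter (adjusted p = 3.17e-03). The recombinase genes RAG1 and RAG2, which overlap on opposite strands, fell by 1.80 ± 0.09 and 1.98 ± 0.20. CD4 fell by 1.43 ± 0.08 and the CD1 genes CD1B, CD1C and CD1E by 0.36, 0.52 and 0.45. The receptor genes CD3D and CD3E rose by 0.17 ± 0.04 and 0.21 ± 0.06.

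**Figure D3:**
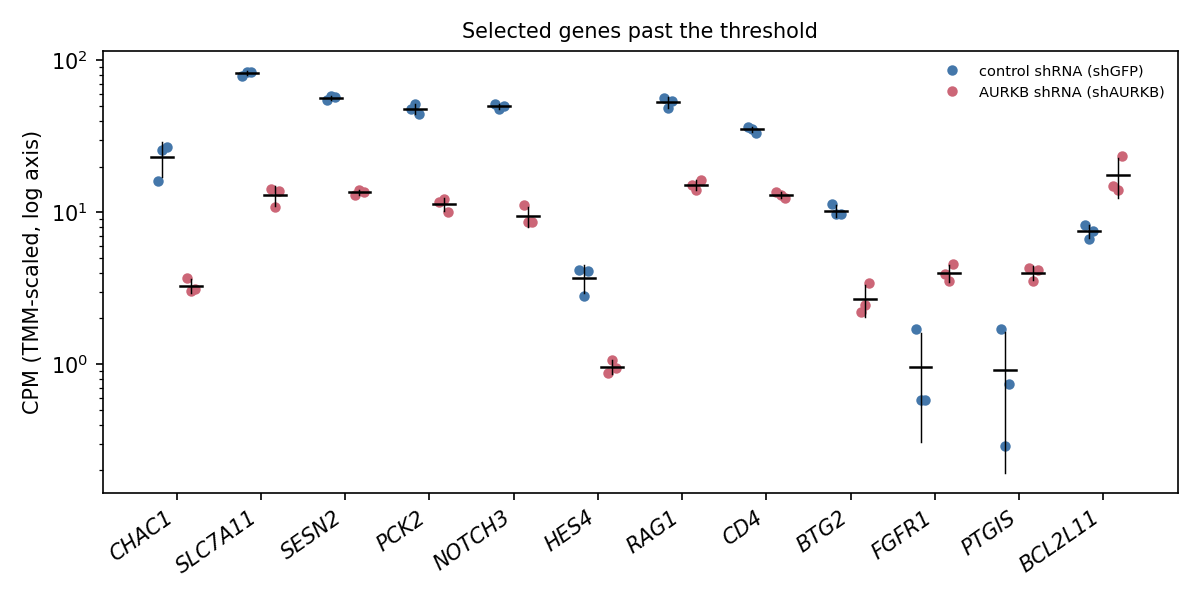
CPM per library (log axis) of 12 called genes with control shRNA (blue, n = 3) and AURKB shRNA (red, n = 3); horizontal bars are means and vertical bars 1 SD either side, and some genes were chosen after their values were seen. SLC7A11 was 82.4 CPM in the controls and 13 CPM with AURKB shRNA on average, and FGFR1 0.953 and 4 CPM.

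Targets of p53 rose in part. Of 28 tested, 11 rose and 2 fell, and 12 rose and 3 fell when adjusted over the list alone (median 0.13, camera adjusted p = 0.0301, but adjusted p = 0.137 with an estimated correlation). The fallers named by the rule, SESN2 (-2.07 ± 0.07) and BTG2, also belong to the stress-response and MYC-repressed lists. In the BCL2 family, which sets the threshold for apoptosis, 4 of 13 tested genes rose and 2 fell, with the same counts when adjusted over the list alone. The list, with a median of 0.12, was not called by camera (adjusted p = 0.321) but was called higher by fry (adjusted p = 0.0195). The pro-apoptotic genes BCL2L11 (BIM) and BAX rose by 1.23 ± 0.22 and 0.78 ± 0.06. The anti-apoptotic genes BCL2 and MCL1 fell by 0.19 ± 0.05 and 0.23 ± 0.04. The 7 not called were the anti-apoptotic BCL2L1 (0.07) and BCL2L2 (-0.58) and the pro-apoptotic BAK1 (0.37), BBC3 (0.14), BIK (0.12), PMAIP1 (-0.32) and BMF (-1.26).

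Lists of cell cycle genes were not called by camera. Among 43 genes of G2 and mitosis, 11 rose, 6 fell and 26 were not called (median 0.01, or -0.04 with upper-quartile scaling, camera adjusted p = 0.608), with 11 and 6 also when adjusted over the list alone. CDC20, the anaphase activator gene, rose by 0.44 ± 0.04 and CCNB1, cyclin B1, by 0.42 ± 0.05. CENPE and ASPM, spindle genes chosen after their values were seen, fell by 0.38 ± 0.07 and 0.38 ± 0.04. Of 46 DNA replication genes, 4 rose and 1 fell, also when adjusted over the list alone (median 0, or -0.05 with upper-quartile scaling, camera adjusted p = 0.812). With a trend on abundance, length and GC content removed, that median was -0.12. SLBP, the histone mRNA binding protein gene, rose by 0.32 ± 0.08, a call that was lost without any 1 of the controls or without shAURKB replicate 2 (adjusted p = 0.0599 to 0.0799) and with upper-quartile scaling (adjusted p = 0.0585). POLE fell by 0.30 ± 0.04. Of 31 listed replication-dependent histone genes, 14 were tested. Among these 1 fell, the linker histone gene HIST1H1C (-0.99 ± 0.19, edgeR adjusted p = 0.0125, but 0.056 with DESeq2), which shares its span with HIST1H2BB. None rose (list median -0.20, camera adjusted p = 0.608). The tested histone genes lay low, with HIST1H2BK the highest at 9.36 CPM in the controls. How fully the libraries captured them was not tested, so absent calls do not show unchanged levels.

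Lists of metabolic, ribosomal protein and mitochondrially encoded genes had medians of -0.13 to 0.18. In nucleotide synthesis, 9 of 19 genes rose and none fell, and 13 rose when adjusted over the list alone (median 0.17, camera adjusted p = 1.58e-03, but adjusted p = 0.0835 with an estimated correlation). IMPDH1, of guanine nucleotide synthesis, rose by 0.44 ± 0.12, a call lost with upper-quartile scaling (adjusted p = 0.063) and without any library other than shGFP replicate 1 (adjusted p = 0.0568 to 0.113). NME1, which overlaps the read-through gene NME1-NME2, rose by 0.41 ± 0.06. Among 22 glycolysis genes, 5 rose and 3 fell, and 7 and 4 when adjusted over the list alone (camera adjusted p = 0.444; median 0.09). HK2, shared with the MYC-induced list, and the glucose transporter gene SLC2A1 (0.55 ± 0.07) rose. In cholesterol synthesis, 6 of 24 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.0875, but 0.0467 without shAURKB replicate 1 and 0.0105 with no low-count filter; median 0.18). INSIG1, a regulator of the pathway, fell by 0.41 ± 0.04. Cytosolic ribosomal protein genes rose in 23 of 78 cases and fell in none, or 29 when adjusted over the list alone (median 0.14, camera adjusted p = 5.11e-06, but adjusted p = 0.0835 with an estimated correlation). RPS15 and RPS13 both rose by 0.46, with errors of 0.13 and 0.09, and such genes can share reads with processed pseudogenes. The call of RPS15 was lost without any library other than shGFP replicate 1 (adjusted p = 0.0559 to 0.111), and that of RPS13, which lies in the span of PIK3C2A, without shGFP replicate 3 (adjusted p = 0.0517). With a trend on abundance, length and GC content removed, the median of the ribosomal protein list was 0.01. Of 13 mitochondrially encoded genes, 8 fell and 2 rose, also when adjusted over the list alone (median -0.13; camera adjusted p = 0.048, but adjusted p = 0.67 with an estimated correlation and 0.0672 to 0.21 without shGFP replicate 2 or 3 or without shAURKB replicate 2 or 3, over a range of 6.45e-03 to 0.67 across the alternatives). MT-ND2 rose by 0.50 ± 0.03 and MT-CO2 fell by 0.28 ± 0.03.

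Lists of immune response genes were not called by camera. Among 34 interferon response genes, 4 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.608; median -0.08). OAS2 rose by 0.91 ± 0.09 and OAS1 fell by 0.81 ± 0.22, the latter a call lost without any library other than shGFP replicate 3 (adjusted p = 0.0502 to 0.107). Of 18 immediate early and NF-kB response genes, 4 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.911; median 0.07). JUN rose by 0.96 ± 0.18 and EGR1 fell by 0.85 ± 0.05. Markers of other cell types were scarce. Of 10 B-cell markers 2 were tested and neither was called, with CD79A at -0.22 ± 0.10 (edgeR adjusted p = 0.158). The single tested marker of 17 for myeloid and erythroid cells, CD68, had a log2 fold change of 0.17 ± 0.29 (edgeR adjusted p = 0.725). Fibroblast and epithelial markers summed to 10.3 ± 15.9 CPM in the controls and 1.18 ± 0.328 CPM with AURKB shRNA (SD, n = 3), the control value resting on shGFP replicate 1.

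The deposited FPKM gave a second unit for the same libraries. With limma-trend on log2(FPKM + 1), 2546 of the 3456 genes called from counts were called in the same direction, 73.7% (exact 95% binomial interval 72.2 to 75.1%, which treats genes as independent). The share was 53.6% without the FPKM filter and 61.7 to 65.2% with a library left out, outside that interval. FPKM gave 1264 higher and 1686 lower genes, with 9 and 45 at 2-fold, on a log2(FPKM + 1) scale that understates the change of low genes.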

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

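Centring on abundant genes was the single alternative chosen after seeing the data; it moves each gene by the same 0.043 and so tests no call. Across the alternatives, AURKB stayed called (log2 fold change -1.42 to -1.28) and MYC uncalled (adjusted p 0.162 to 0.952), with MYC at -0.128 to 0.361 when 1 library was left out and reversed without shAURKB replicate 1. The MYC-induced and integrated stress response lists kept their direction and call in all 14 settings (highest adjusted p 3.72e-03 for each). Leaving out each library gave 998 to 1056 lower genes, 2 to 5 lower lists, adjusted p of 0.0146 to 0.0657 for NOTCH1 targets and 0.0245 to 0.21 for mitochondrially encoded genes, and an FPKM share of 61.7 to 65.2%. DESeq2 called 1062 lower genes, and in simulation 19.3% of its calls were unchanged genes, against 7.1% with edgeR. limma-trend on log2(FPKM + 1) had 9 higher and 45 lower genes at 2-fold, since the added 1 shrinks low genes. Without a filter the FPKM share was 53.6% and the adjusted p of mitochondrially encoded genes 0.117, and limma-voom gave 0.388 for NOTCH1 targets; the cause was not tested. CDCA8 was reversed at -0.035 with upper-quartile factors and -0.031 from FPKM, uncalled in both. An estimated correlation left 1 list higher and 1 lower, with adjusted p of 0.088 (MYC-repressed), 0.19 (NOTCH1), 0.137 (p53), 0.0835 (nucleotide synthesis and ribosomal proteins) and 0.67 (mitochondrially encoded). fry, which compares no list with other genes, called 7 lower. Among lists that camera did not call, fry called the BCL2 family (adjusted p = 0.0195) and cholesterol synthesis (adjusted p = 1.77e-03) higher. It called the Aurora complex (adjusted p = 9.34e-03), interferon response (adjusted p = 0.0266) and T-cell lists (adjusted p = 2.65e-03) lower. Among named genes, 46 settings of single genes lost a call, 30 of them with a library left out, chiefly of AURKA, OAS1, IMPDH1, RPS15 and SLBP. DESeq2 gave no adjusted p for 5 named genes.

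The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.089, -0.031 and -0.037, and 0 of 3 controls correlated best with its own number. With the replicate block, 1286 genes were higher and 1027 lower, 2 lists were lower, the adjusted p was 0.103 for NOTCH1 targets and 0.0776 for mitochondrially encoded genes, and the FPKM share was 38.9%.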

Other observations

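A further 5 gene groups were listed and tested after the data were seen. Of 25 cytosolic chaperone genes, 21 rose and none fell (median log2 fold change 0.46, camera adjusted p = 4.4e-25, and adjusted p = 2.08e-03 with an estimated correlation). HSP90AA1 rose by 0.67 ± 0.05, HSPA8 by 0.64 ± 0.03 and DNAJA1 by 0.75 ± 0.03. Of 18 endoplasmic reticulum chaperone genes, 11 rose and 1 fell (median 0.38, camera adjusted p = 3.45e-07, but adjusted p = 0.0553 with an estimated correlation). HSPA5 (BiP) rose by 0.81 ± 0.03, and EDEM1, of the degradation pathway, fell by 0.90 ± 0.03. Among 14 hypoxia response genes 9 fell and none rose (median -0.58, camera adjusted p = 4.49e-09, and adjusted p = 0.0104 with an estimated correlation). VEGFA fell by 1.85 ± 0.16 and BNIP3 by 0.61 ± 0.07. Of 18 FOXO-induced and quiescence genes 9 fell and 1 rose (median -0.65, camera adjusted p = 2.24e-07, and adjusted p = 0.012 with an estimated correlation). The cyclin kinase inhibitor gene CDKN2C fell by 1.72 ± 0.07, and KLF2 was the riser (1.2 ± 0.11). Of 20 cytosolic aminoacyl-tRNA synthetase genes 7 rose and 7 fell (camera adjusted p = 0.179; median -0.04), with CARS at -0.78 ± 0.05 and VARS at 0.38.

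Of the tests below, those of library scaling, of the hypoxia list, of marker reads, of depth and of the calls without a control were chosen after their results were seen. The marker test was first set on the whole fibroblast and epithelial list and came out in favour of such cells, with a summed level 18.6 times that of the highest other library. It was parted into epithelial and fibroblast genes after that value was seen, because COL1A2 made up 17.8 of the 28.69 CPM. MYC-induced genes rose. MYC mRNA did not pass the test, which does not exclude a rise of its own (0.12 ± 0.25, SE), and MYC protein was not measured. A trend with abundance, gene length and GC content is argued against as the whole cause: with the trend removed, the list's median was 0.33, above all of 10000 random lists matched on abundance (their central 99% ran from -0.09 to 0.09). The same removal took the ribosomal protein list from 0.14 to 0.01, so its rise may follow that trend, and the DNA replication list from 0 to -0.12, lower than 99% of its matched random lists (-0.10 to 0.10). Library scaling moves all genes alike, so it is argued against as the source of a gap between lists. The median of the DNA replication genes lay 0.42 below that of the MYC-induced genes. Such a gap hardly depends on the scaling, so it cannot show whether the MYC-induced genes rose or other genes fell. A difference in growth state between the arms stays open beside an effect of the shRNA, whether or not through AURKB loss, since the arm is the single factor of the design.

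Integrated stress response genes fell. With the same trend removed their median was -0.66, below all of 10000 matched random lists, which argues against abundance, length and GC content as the cause. Hypoxia response genes fell too, by a median of -0.58. Glycolysis genes did not follow, since of 22 tested 5 rose and 3 fell (camera adjusted p = 0.444). Medium or cell density differing between the arms may account for the falls of the stress response and hypoxia lists. This cannot be told apart from an effect of the shRNA, because each arm has a single condition and no measure of density was used here.

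In shGFP replicate 1, 120 genes had at least 5 reads and none in the other libraries, among them TM4SF1 (67 reads), IGF2BP2 (47), HOXB9 (45) and SHROOM3 (45), all named after their values were seen. Greater depth is argued against, since its total count was 0.948 of the mean of the others. Fibroblast RNA is argued against, since COL1A1, COL3A1, DCN, LUM and PDGFRB together had 1 read beside 185 of COL1A2, although CAV1, in the same marker list, had 16 reads against at most 2 in any other library. RNA of epithelial cells may be present: KRT8, KRT18 and KRT19 together had 95 reads, at most 5 in any other library. EPCAM and CDH1 together had 2, which keeps it open. No explanation beyond depth, fibroblast RNA and epithelial RNA was tested. RNA of other cells is argued against for 187 of the 268 genes at least 2-fold lower, which were called lower with this library left out. For the other 81 it cannot be told apart from the loss of a library, since 79 and 80 genes were not called without shGFP replicate 2 or 3. The test first planned, the median log2 ratio of this library to the other controls over the 268 genes (0.032), decides nothing, because the call itself favours genes on which the controls are alike.

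The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 1847 higher, 1609 lower, 37 higher at 2-fold and 268 lower at 2-fold, where the highest count in either direction in another split was 3. It called 8 lists, and each other split called 2 or 3. Every other split mixes the arms, so a difference between the arms widens the spread within its groups. Their gene counts therefore give no level to expect without an effect. A count as large came from 1 split, the real one, in each case.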
